A study of Drosophila melanogaster with 2 samples.

How the data were processed

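Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole embryos of a transgenic Drosophila melanogaster line in which Ash1 carries GFP at its C terminus. Per the labels, embryos of both sexes were collected at 0 to 24 h of development, chromatin was sheared by sonication, and fragments of 200 to 800 bp were used. The 2 samples are biological replicates 2 and 4 of a single group, and no second condition or untagged strain was analysed here. Free text in the labels of both samples calls them input controls, whereas the antibody (ash1), the assay name and the peak calls describe immunoprecipitated material. They were treated as Ash1-GFP ChIP samples on that ground.

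The authors deposited 4 peak lists in dm6 coordinates. A list of 30000 candidate regions, peaks and background together, was made from each replicate, and another from the alignments of both replicates pooled. Per the text deposited with the files, each was called against 1 control alignment, shared by both replicates. The remaining list holds 1567 regions that passed an irreproducible discovery rate (IDR) threshold, and they are called peaks here. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. The deposited signal value of a region is the peak caller's own measure of enrichment over the control. Its scale is not stated, so it served to rank regions within a list, and ratios of it, given for the strongest region alone, hold on that scale only. The deposited −log10 q-value reached its highest value in 3537 of the pooled candidates, among them all 1567 peaks, and was therefore not used for ranking. The other deposited columns used were the start, the end and the summit offset, in bp from the start. Coordinates are printed 1-based. The lists hold no read counts, so the sequencing depth is unknown, and no interval given here includes read sampling.

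The 1567 peaks were exactly the 1567 pooled candidates with the highest signal values. The lowest signal among them was 92.53 and the highest below them 92.52. The other 28433 candidates, which could have passed, formed the background of each test of peaks. Because every candidate list has 30000 regions, ranks were set side by side between replicates. The most frequent region width was 336 bp in the pooled list, 400 bp in replicate 2 and 270 bp in replicate 4.

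Genes, transcription start sites (TSSs) and exons came from the Ensembl release 115 annotation, and sequence from the RefSeq copy of the same assembly. Annotated transposable elements were left out. No region reached past the end of a chromosome arm. A peak was assigned to a promoter when its summit lay within 500 bp of an annotated TSS, and a gene was called bound when a peak lay within that distance of any of its TSSs. A peak could count for several genes. Other summits were classed, in this order, as 5' UTR, coding exon, 3' UTR, noncoding exon, intron or intergenic. Replicates were compared by the share of the 1567 strongest candidates of replicate 2 with a summit within 100 bp of one of the 1567 strongest of replicate 4. Ranks were shuffled 1000 times to give the share without any relation of rank, which does not allow for the control shared by both replicates.

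Peaks were compared with the other candidates by two-sided Fisher exact tests, with conditional odds ratios and exact 95% intervals. Binomial 95% intervals of shares are Clopper-Pearson. Tests covered the promoter share, 6 chromosome arms, the share in the Hox complexes, the share within 500 bp of tRNA genes, 22 gene lists and 16 sequence motifs found on either strand within 100 bp of the summit. The Y chromosome held no candidate. Each gene list was compared with the remaining ones of the 7494 genes that had a candidate at a TSS, by bound genes, and the replication-dependent histone genes had none. Benjamini-Hochberg adjustment was made within arms, lists and motifs, at a threshold of 0.05. Genes and peaks are not independent replicates, so p-values describe these lists and not the spread between embryo collections. Tests stratified by promoter and by GC content, in 5 classes of equal size, used the Cochran-Mantel-Haenszel method.

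Tests, gene lists, motifs, alternatives and the genes to be named were fixed before the data were examined. Named are ash1, the genes with the TSS nearest to the 20 strongest peaks, all Hox genes, the Polycomb and trithorax group members, and at most 4 bound genes of each other list. Genes named outside this rule are identified as such. For 9 list symbols a synonym matched the annotation. calypso and nos were left out because no annotated symbol matched them. The alternatives were a stricter threshold, each replicate alone (its 1567 strongest candidates against its others), a narrower background, other distances, all annotated genes as background, protein-coding genes only, merging of regions under 1000 bp apart, and stratified motif tests. Alternatives added later counted nearest genes only, stratified genes by number of TSSs, restricted the Hox test to summits away from a TSS, or kept only peaks among the 1567 strongest candidates of both replicates. The location classes other than the promoter were also added later.

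Procedures were tested on simulated data. Over 100 draws on the 7494 genes, a planted odds ratio of 8 was called in 100% of draws for the ribosomal protein list and 91% for the Polycomb group list. An odds ratio of 4 was called in 89% for the other Polycomb-target regulators, and 0.2 in 90% for tRNA genes. Lists without a planted effect were called in 0.5% of tests. Each gene was drawn independently there, whereas 273 peaks of the data had 2 or more genes in reach, so this rate may be too low. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6.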

Results

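Binding of Ash1, a trithorax group histone methyltransferase that acts on lysine 36 of histone H3, was mapped in Drosophila embryos that express it fused to GFP. The data comprised 2 biological replicates, replicates 2 and 4, of 1 group, with 30000 candidate regions each, 30000 from both replicates pooled, and 1567 pooled regions that passed the authors' IDR threshold. Ranks below follow the authors' signal value, with 1 the strongest. All coordinates are in dm6. With a single group, the comparisons concern the replicates with each other and the peaks with the candidates that did not pass.

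The strongest region lay beside ash1 itself. Its 314 bp, at 19590464 to 19590777 on 3L, held rank 1 in the pooled list and in both replicates. The summit, at 19590611, fell in the 248 bp between ash1 (19590773 to 19598755, minus strand) and CG14100 (19589072 to 19590524). It was 162 bp beyond the annotated 3' end of ash1, 8144 bp from the nearest ash1 TSS and 87 bp from the TSS of CG14100. On the authors' signal scale, which is not stated, its value of 1593 was 1.86 times that of the second strongest region, at Ugalt, and the corresponding ratio was 1.48 in replicate 2 and 1.87 in replicate 4. No candidate lay within 500 bp of a TSS of ash1, and the strongest of the 4 candidates inside the gene ranked 6612 (signal 48.8). The labels place GFP at the C terminus of Ash1, but do not say whether the tagged gene is an extra copy or the endogenous one.

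**Figure D1:**
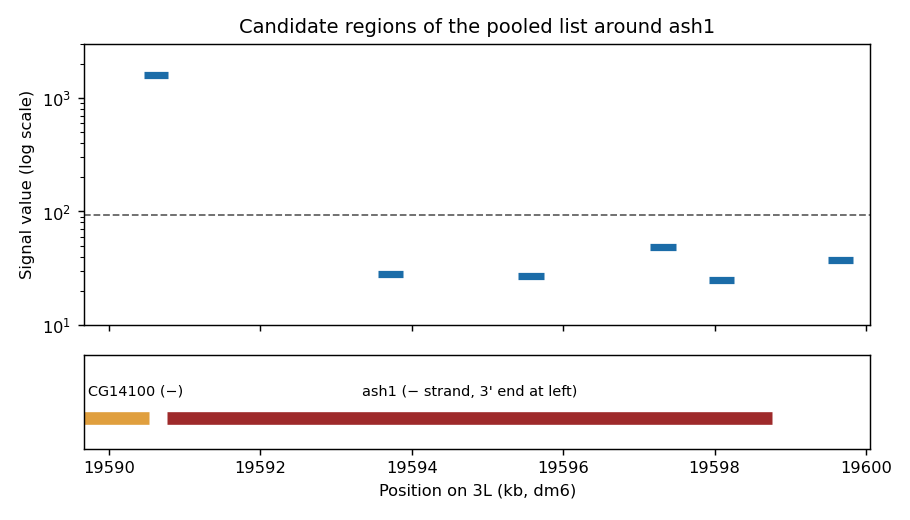
Candidate regions of the pooled list (blue bars, position on 3L in kb against signal value on a log scale) around ash1, with ash1 and CG14100 drawn to scale in the lower panel. The region between the genes has a signal of 1593, and the regions inside ash1 lie below the dashed line, the lowest signal among the peaks (92.53).

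Of the 20 strongest peaks, 13 lay at a promoter, with the peak between ash1 and CG14100 counted among them, and 7 in an intron. The other promoter summits lay at Ugalt, a UDP-galactose transporter (rank 2, 43 bp from the TSS), CG1888, lncRNA:CR31840, RpL7, Alg3, RpS27, fkh, CenG1A, Hsp83, px, PNPase and mRpL41. RpL7 and RpS27 encode ribosomal proteins, fkh the transcription factor Fork head and Hsp83 the Hsp90 chaperone. The intronic summits had their nearest TSS at cbt (rank 3, 1452 bp away), sbb, CG11050, ph-p, CG9663, Lk6 and CG32772. The summit nearest to cbt lay in an intron of ush, a gene outside the naming rule, and the others in the gene named. The summit in ph-p, a Polycomb group gene, was 501 bp from its TSS (rank 8). In the individual replicates these 20 regions ranked no lower than 50 in replicate 2 and 38 in replicate 4.

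The first comparison asked how far the replicates shared their strongest regions. Regions at ash1, Ugalt, cbt, sbb, CG1888 and lncRNA:CR31840 were among the 10 strongest of both replicates, whereas RpL7 ranked 50 in replicate 2 and 3 in replicate 4. Of the 1567 strongest candidates of replicate 2, 711 (45.4%, 95% interval 42.9 to 47.9) had a summit within 100 bp of one of the 1567 strongest of replicate 4. Shuffled ranks gave a mean of 61.4 and at most 83 shared regions. Ranks of the 9170 candidates found in both lists had a Spearman rho of 0.54, across regions that are not independent replicates. Both replicates were called against the same control, which neither the shuffled ranks nor rho take into account. Of the 20, 100 and 500 strongest regions of replicate 2, 10 (50%), 51 (51%) and 249 (49.8%) were among as many of replicate 4. In the pooled list, which is ranked on both replicates together, the 20 strongest peaks were all among the 1567 strongest candidates of each replicate, as were 97 of the 100 strongest and 430 of the 500 strongest. Over all peaks the number was 726 (46.3%), and 113 (7.21%) were among the strongest candidates of neither replicate. With summits within 50 bp or 250 bp, the shared percentage was 36.7 or 52.8.

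**Figure D2:**
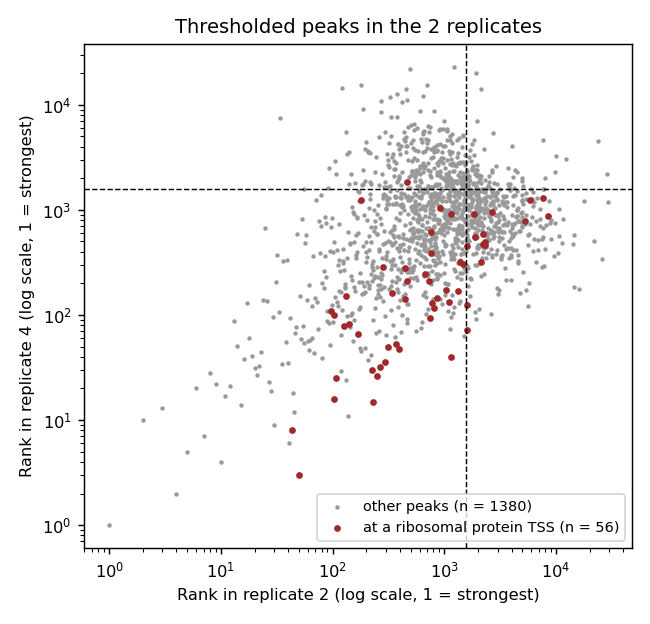
Rank in replicate 2 against rank in replicate 4 (both log scales, 1 the strongest) of the 1436 peaks with a candidate in both replicates; 56 of them, in red, lie at the TSS of a cytoplasmic ribosomal protein gene. Dashed lines mark rank 1567, and most red points lie below the diagonal, at stronger ranks in replicate 4 than in replicate 2.

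The second comparison asked where in genes the peaks lay. Promoters held 914 of the 1567 peaks (58.3%, 95% interval 55.8 to 60.8) and 7531 of the 28433 other candidates (26.5%), an odds ratio of 3.88 (95% interval 3.50 to 4.32, p = 1.94e-145, two-sided Fisher exact test). Coding exons were nearly free of peaks, with 12 (0.766%) against 12.4% of other candidates, an odds ratio of 0.0546 (0.0281 to 0.0959, adjusted exact p = 3.33e-68). Peaks were also less frequent in introns (28.8% against 40.5%, odds ratio 0.596, adjusted exact p = 2.87e-20), between genes (8.998% against 16.2%, odds ratio 0.511, adjusted p = 8.83e-16) and in 3' UTRs (10 peaks, odds ratio 0.374, adjusted p = 9.03e-04). Each summit had a single class and promoters were assigned first, so the larger promoter share by itself lowers the others. Of the 653 peaks and 20902 other candidates away from a TSS, introns held 452 and 11511, a larger share of the peaks. Intergenic sequence held 141 and 4610, close shares, and coding exons 12 and 3519, a smaller share of the peaks. The promoter share was 67% over the 100 strongest regions, 56.8% at ranks 501 to 1567 and 20.4% at ranks 15001 to 30000. The coding exon share was 2% over the 100 strongest, 0.75% at ranks 101 to 500, 0.656% at ranks 501 to 1567 and 17.1% at ranks 15001 to 30000. The median distance from summit to TSS was 259 bp for peaks and 1568 bp for other candidates. The 3' UTR difference did not hold for peaks strong in both replicates (odds ratio 0.485, adjusted exact p = 0.108), and the coding exon odds ratio was 0.0985 without replicate 4.

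**Figure D3:**
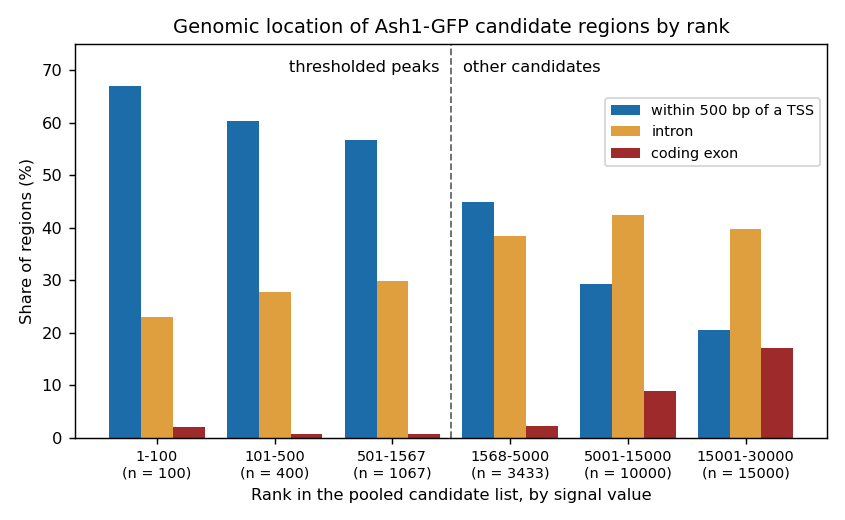
Share of candidate regions (%) at a promoter, in an intron or in a coding exon, by rank in the pooled list, with the number of regions under each group of bars. The promoter share is 67% at ranks 1 to 100 and 20.4% at ranks 15001 to 30000, and the coding exon share is 2% and 17.1% in the same groups. The coding exon share is lowest, 0.656%, at ranks 501 to 1567.

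Of the 6 chromosome arms, none passed the adjusted threshold in Fisher exact tests of its share of peaks, and 3L alone had an unadjusted p below 0.05 (294 peaks, odds ratio 0.851, p = 0.0145, adjusted p = 0.0871). Arm 4 held 18 peaks (odds ratio 1.48, adjusted exact p = 0.236) and the X chromosome 249 (odds ratio 0.957, adjusted p = 0.662). In replicate 4 alone, 3L passed with an odds ratio of 0.826 (adjusted exact p = 0.0239). With regions under 1000 bp apart merged, 3R passed with 1.22 (adjusted exact p = 0.0140).

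The next comparison asked which classes of genes carried promoter peaks. Of 7494 genes with a candidate at a TSS, 1157 (15.4%) were bound, 1044 of them protein coding and 95 noncoding RNA genes. Cytoplasmic ribosomal protein genes stood highest, with 58 of 79 bound (73.4%), an odds ratio of 15.9 (95% interval 9.44 to 27.6, adjusted exact p = 1.54e-29 over the 22 lists). The strongest were RpL7 (rank 9), RpS27 (rank 11), RpL14 (rank 32) and RpL23A (rank 36). Without replicate 4 the odds ratio of the list was 8.02, with 46 of 80 genes bound, and with all annotated genes as background it was 25.7.

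Polycomb group genes, which encode repressors that act against the trithorax group, were the other list with a higher share, 8 of 15 genes (53.3%, odds ratio 6.29, 95% interval 1.99 to 20.4, adjusted exact p = 0.00807). Bound were ph-p and ph-d, paralogues that encode Polyhomeotic proteins (ranks 240 and 317), lolal (rank 415), Kdm2 (rank 447), E(z), the histone H3 lysine 27 methyltransferase (rank 700), Su(z)2 (rank 736), Jarid2 (rank 853) and Psc (rank 1342). Of these bound genes, ph-p and ph-d lie close together on X, and Psc and Su(z)2 on 2R. The exact test counts such neighbours as separate genes, although they are not independent loci. Candidates at jing, Sfmbt, Su(z)12, Scm, Caf1-55, Pc and escl did not pass, and Pc, the gene of the founding member, ranked 13056. Asx, Pcl, Sce, Spps, crm, esc, pho, phol and sxc had no candidate at a TSS. The list passed in replicate 2 alone and in replicate 4 alone (odds ratios 5.11 and 7.18), with 8 genes bound in each and 7 in both. E(z) counted in replicate 2 alone (rank 1610 in replicate 4) and Sfmbt in replicate 4 alone (rank 943). Within 100 bp of the peak summit, Kdm2 and Psc had no candidate in replicate 2 and Su(z)2 none in replicate 4, although other candidates at their TSSs ranked 994, 1116 and 761 there. When only peaks matched within 100 bp to the strongest candidates of both replicates counted, 4 of 15 genes were bound and the list no longer passed (odds ratio 4.45, adjusted exact p = 0.172).

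In the trithorax group, 6 of 19 genes were bound (31.6%, odds ratio 2.54, 95% interval 0.789 to 7.17, adjusted exact p = 0.311). They were brm, the ATPase of the Brahma chromatin remodelling complex (rank 116), tna (rank 372), fs(1)h (rank 495), skd (rank 914), Trl, which encodes GAGA factor (rank 1044), and kis (rank 1219). Candidates at Kdm5, mor, E(bx), Rbbp5, nej, MRG15, Bap55, Bap60, Snr1, wds, ash2, trx and e(y)3 did not pass. No candidate was found at a TSS of ash1, Bap111, Dpy-30L1, Set1, Utx, dom, kto, osa, trr or vtd. Each replicate alone had 5 bound genes, with brm, tna and fs(1)h bound in both. In replicate 4 alone Trl and kis no longer counted (ranks 1998 and 2568) and Kdm5 did (rank 1106), whereas skd did not in replicate 2 alone (rank 7721). With all annotated genes as background the list passed (odds ratio 3.87, adjusted exact p = 0.0247).

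**Figure D4:**
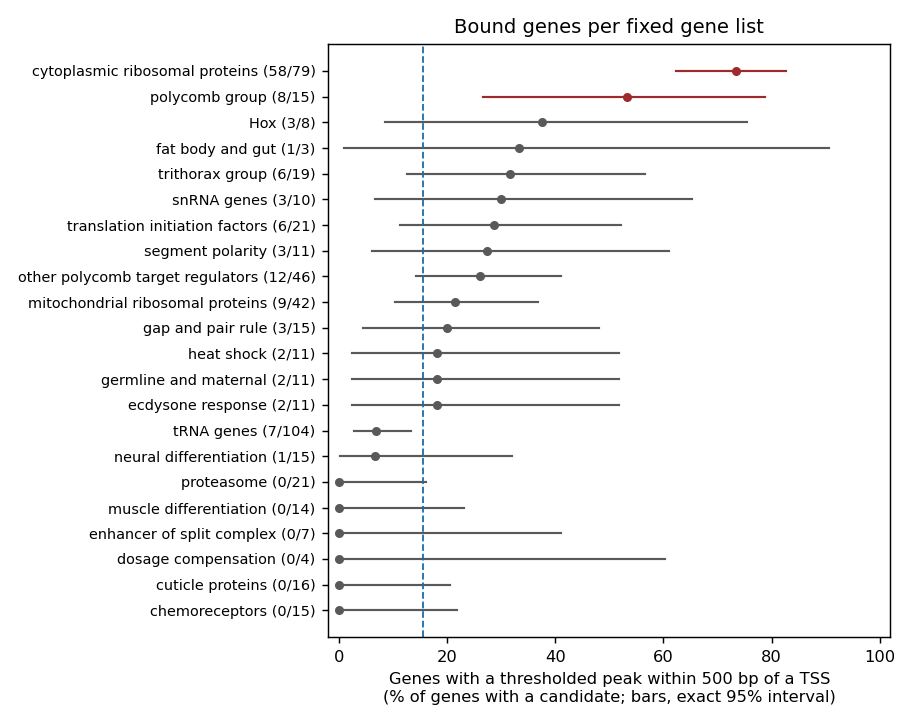
Share of genes with a promoter peak (%, points) among the genes of each list with a candidate, with exact 95% binomial intervals (bars) and the number of genes. Red marks the 2 lists past the adjusted threshold, cytoplasmic ribosomal proteins (73.4%) and Polycomb group (53.3%), and the dashed line is the share over all genes with a candidate (15.4%).

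Lists of other developmental regulators did not pass the adjusted threshold. Of 46 further genes of transcriptional regulators known as Polycomb targets, 12 were bound (odds ratio 1.94, adjusted exact p = 0.274), led by hth (rank 47), grn (rank 497), tin (rank 590) and cad (rank 731). With nearest genes only, this list passed (odds ratio 2.66, adjusted exact p = 0.0486), as it did with all annotated genes as background (4.59, adjusted p = 4.27e-04). With peaks strong in both replicates 3 of 46 were bound (0.848, adjusted exact p = 1). Bound segment polarity genes were ci (rank 49), nkd and fz, 3 of 11 (odds ratio 2.06, adjusted exact p = 0.580; 1.14 in replicate 2 alone and 1.07 in replicate 4 alone). Bound gap and pair-rule genes were slp1, slp2 and opa, 3 of 15 (odds ratio 1.37, adjusted exact p = 0.751). Odds ratios under the 12 alternatives were 1.07 to 4.94 for segment polarity and 0.893 to 2.96 for gap and pair-rule genes, and neither list passed in any. No gene of the Enhancer of split complex was bound, out of 7 (upper 95% bound of the odds ratio 3.80).

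Housekeeping lists other than the cytoplasmic ribosomal proteins were not past the threshold. Mitochondrial ribosomal protein genes had 9 of 42 bound (odds ratio 1.498, adjusted exact p = 0.479), with mRpS23 (rank 14, a peak nearer to CenG1A) and mRpL41 (rank 19) the strongest. Translation initiation factor genes had 6 of 21 (odds ratio 2.20, adjusted exact p = 0.311), with eIF6 at rank 27, and proteasome genes 0 of 21 (upper 95% bound 1.05, adjusted p = 0.274). With nearest genes only, 3 mitochondrial ribosomal protein genes and 2 initiation factor genes were bound, and the odds ratios fell below 1 (0.574 and 0.787, adjusted exact p = 0.613 and 1). The mitochondrial list was at 0.917 in replicate 4 alone and the initiation factor list at 1.36 in replicate 2 alone, and their highest values under the 12 alternatives were 2.09 and 3.37.

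None of the lists of differentiated tissues passed the threshold in the main test, and the lists were not tested together. No muscle (0 of 14), cuticle protein (0 of 16) or chemoreceptor gene (0 of 15) was bound, with upper 95% bounds of the odds ratio of 1.65, 1.42 and 1.53 and an adjusted exact p of 0.311 each. With all annotated genes as background the cuticle protein and chemoreceptor lists passed, with fewer bound genes (upper 95% bounds 0.498 and 0.305, adjusted exact p = 0.00493 and 1.82e-04). Of 15 neural genes elav was bound (rank 396; odds ratio 0.391, adjusted exact p = 0.678), and of 3 fat body and gut genes fkh (rank 12; 2.74, adjusted p = 0.580). Also bound were bgcn and bcd of 11 germline and maternal genes, Hsp83 and Hsp27 of 11 heat shock genes, and Eip75B and ftz-f1 of 11 ecdysone response genes, each list with an odds ratio of 1.22 and an adjusted p of 0.751. Germline and heat shock genes were at 2.30 and 2.68 in replicate 4 alone, and ecdysone response genes at 0.635 in replicate 2 alone. Fat body and gut genes were at 11.4 in replicate 2 alone, from 2 of 3 genes (95% interval 0.596 to 676). They were at 1.34 in replicate 4 alone. In replicate 4 alone no neural gene was bound, and in replicate 2 alone 1 of 12 muscle genes was. Under the 12 alternatives odds ratios were 1.04 to 2.71 (germline), 0.943 to 2.71 (heat shock), 0 to 2.69 (ecdysone), 0.986 to 11.4 (fat body and gut) and 0 to 0.765 (neural), and none of these lists passed. None of the 4 dosage compensation genes with a candidate was bound (upper 95% bound 8.30).

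Genes of tRNAs and small nuclear RNAs were examined because highly transcribed small RNA genes are frequent sites of unspecific ChIP signal. Peaks lay within 500 bp of a tRNA gene in 6 cases (0.383%), against 84 other candidates (0.295%), an odds ratio of 1.30 (95% interval 0.462 to 2.95, exact p = 0.475; 0.636 in replicate 2 alone). By TSS, 7 of 104 tRNA genes were bound (odds ratio 0.392, adjusted exact p = 0.0951), and 3 of 10 snRNA genes (odds ratio 2.35, adjusted p = 0.351; 0.635 in replicate 2 alone, 0 to 3.99 under alternatives). The tRNA list passed, with fewer bound genes, in replicate 2 alone (odds ratio 0.235, adjusted exact p = 0.00202), with nearest genes only (0.219, adjusted p = 0.0142) and with all annotated genes as background (0.362, adjusted p = 0.0107). It did not in replicate 4 alone (0.627, adjusted exact p = 0.452). The exact tests by TSS count neighbouring tRNA genes separately, although several shared a candidate, so they are not independent loci.

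Hox genes, the homeotic genes through which the trithorax group was defined, were examined as genes and as complexes. Promoter peaks lay at Ubx (rank 326, summit 35 bp from the TSS), abd-A (rank 816, 142 bp) and Antp (rank 964, 32 bp). Candidates at lab (rank 1879), Abd-B (rank 2006), Scr (rank 2562), Dfd (rank 2954) and pb (rank 10482) did not pass. The bound share, 3 of 8, was not past the threshold (odds ratio 3.29, 95% interval 0.510 to 16.9, adjusted exact p = 0.311). In replicate 4 alone, where lab and Abd-B also counted, 5 of 8 were bound (odds ratio 8.95, adjusted exact p = 0.0259). In replicate 2 alone, where Scr also counted (rank 698), 4 of 8 were bound and the list did not pass (5.73, adjusted exact p = 0.114). With all annotated genes as background it passed (8.90, adjusted exact p = 0.0285).

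The bithorax complex (3R, 16656623 to 16972236) held 24 peaks, or 7.60 per 100 kb, against 1.14 per 100 kb over all arms. Its strongest summits lay at 16847491 in an intron of lncRNA:iab8 (rank 55), at 16798844 between genes (rank 67), at 16764352 in an intron of lncRNA:bxd (rank 163) and at 16869516 in lncRNA:iab8 (rank 187). These 2 noncoding RNA genes were chosen after their values were seen. The Antennapedia complex (3R, 6661427 to 6999228) held 9 peaks, or 2.66 per 100 kb, the strongest at 6966740 in an intron of Antp (rank 210). Candidates were dense as well, with 363 in the bithorax complex (115 per 100 kb) and 233 in the Antennapedia complex (69.0 per 100 kb), against 21.8 per 100 kb over all arms.

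Set against candidates, no larger share of peaks was detected in the complexes, 33 of 1567 (2.11%) against 563 of 28433 (1.98%), an odds ratio of 1.06 (95% interval 0.723 to 1.52, exact p = 0.710). The test pools the complexes, and no test compared them with each other. Of their candidates, 6.61% passed in the bithorax complex and 3.86% in the Antennapedia complex, against 5.22% over all arms. Away from TSSs the share was higher, with 27 of 653 peaks (4.13%) against 512 of 20902 candidates (2.45%), an odds ratio of 1.72 (1.11 to 2.55, exact p = 0.0104), a test chosen after the data were seen. At promoters it was not, with 6 of 914 against 51 of 7531 (odds ratio 0.969, exact p = 1). With regions under 1000 bp apart merged the odds ratio was 1.93 (exact p = 0.00317). Merging keeps only the strongest of each run of close regions. It removes more of the other candidates where they are dense, as in the complexes, which by itself can raise this odds ratio. Without merging, the odds ratio was 1.44 in replicate 4 alone (exact p = 0.0326) and 0.952 in replicate 2 alone (exact p = 0.858).

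**Figure D5:**
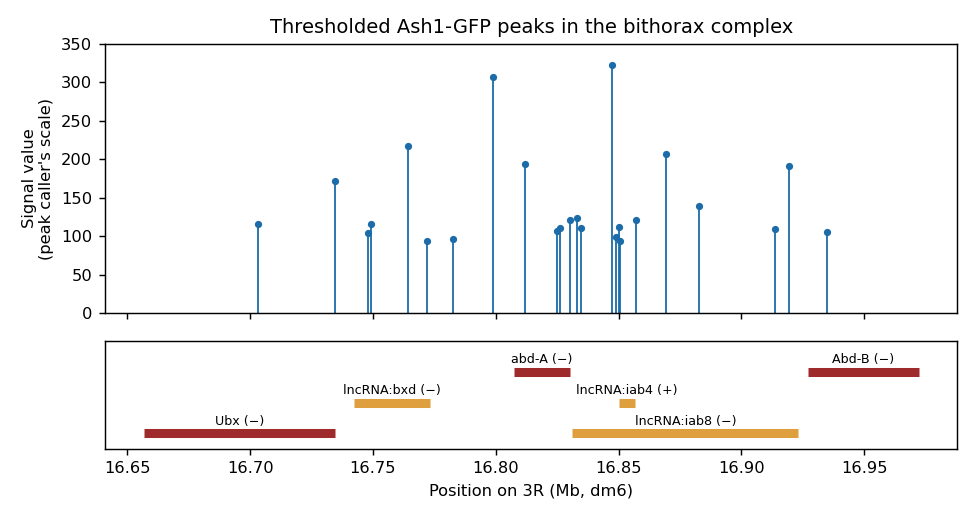
Signal value (peak caller's scale) of the 24 peaks in the bithorax complex against position on 3R (Mb), with Hox genes in red and noncoding RNA genes in orange below. The strongest summits lie in lncRNA:iab8 (rank 55), between lncRNA:bxd and abd-A (rank 67) and in lncRNA:bxd (rank 163).

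Sequence motifs of known DNA-binding factors were counted within 100 bp of the summits. The GAGA factor core GAGAG occurred in 37.5% of peaks and 27.8% of other candidates (odds ratio 1.56, 95% interval 1.40 to 1.73, adjusted exact p = 1.20e-14), and the longer repeat GAGAGAGA in 5.30% and 2.54% (odds ratio 2.15, adjusted p = 1.63e-08). The GT repeat GTGTGT known from Polycomb response elements occurred in 24.4% and 18.8% (odds ratio 1.39, adjusted exact p = 3.91e-07), and the Zeste site in 38.1% and 33.0% (odds ratio 1.25, adjusted p = 9.09e-05). The TATA box core was found in 22.5% of peaks and 15.2% of other candidates (odds ratio 1.62, adjusted exact p = 1.08e-12). These 5 motifs also passed when peaks and candidates were stratified by promoter and GC content, with odds ratios of 1.63, 2.12, 1.42, 1.35 and 1.25. The shuffled control CCGAT also passed then, in the lower direction (0.770). Passing with an odds ratio this near 1 therefore does not by itself point to a binding factor.

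Motifs of housekeeping promoters depended on that stratification. The DNA replication-related element TATCGATA occurred in 4.02% of peaks and 1.34% of other candidates (odds ratio 3.09, adjusted exact p = 2.85e-12), GGTCACAC, bound by M1BP, in 3.06% and 1.40% (odds ratio 2.23, adjusted p = 6.60e-06), and a spaced pair of CGATA in 6 peaks (odds ratio 4.75, adjusted p = 0.00542). Stratified odds ratios, from Cochran-Mantel-Haenszel chi-square tests, were 1.36 (adjusted p = 0.0542), 1.08 (adjusted p = 0.667) and 2.29 (adjusted p = 0.103). The replication-related element was at 1.93 in replicate 2 alone, and in replicate 4 alone the M1BP motif was at 3.45 and the CGATA pair at 11.7. The Pleiohomeotic core GCCAT was less frequent in peaks (33.6% against 38.4%, odds ratio 0.810, adjusted exact p = 2.11e-04) but not after stratification (0.967, adjusted p = 0.633). The Sp1/KLF site was less frequent (odds ratio 0.882, adjusted exact p = 0.0244), and more frequent after stratification (1.14, adjusted p = 0.0445). Without replicate 2 it missed the threshold (0.900, adjusted exact p = 0.0573).

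The shuffled Pleiohomeotic core CCGAT, a control, was itself less frequent in peaks (odds ratio 0.769, adjusted exact p = 6.08e-05), also after stratification (0.770). The shuffled replication-related element was not (odds ratio 0.779, adjusted exact p = 0.626). Neither did the E-boxes CAGCTG (odds ratio 1.12, adjusted exact p = 0.203) and CACGTG (1.32, adjusted p = 0.0559), the Zelda site (0.840, adjusted p = 0.557) or the initiator (1.05, adjusted p = 0.508) pass. In replicate 4 alone CAGCTG passed (1.195, adjusted exact p = 0.0295). Mean GC content around the summit was 43.7% ± 7.83 (SD, n = 1567) in peaks and 46.3% ± 7.82 (SD, n = 28433) in other candidates.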

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

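Tests chosen after the data were seen are the Hox test away from TSSs, the counts with nearest genes only or with peaks strong in both replicates, the stratification by number of TSSs, and the location classes. Of 55 values of whole comparisons under alternatives, 44 stayed on their side of the threshold or within the stated range. The promoter share passed in each alternative run (odds ratio 2.87 to 4.26), the tRNA share in none (0.636 to 1.93). The Hox complexes had an odds ratio of 0.952 to 1.44 with 1 replicate left out and 1.72 away from TSSs. With merged regions it was 1.93, where merging itself thins the dense candidates of the complexes most. The number of arms past the threshold was 0 to 1 with 1 replicate left out and 1 (3R) after merging. Gene lists past the threshold numbered 9 with all annotated genes as background (5 with a higher and 4 with a lower share), 4 with nearest genes only and 1 with peaks strong in both replicates, where fewer peaks entered the test. The ribosomal protein list passed in each alternative (odds ratio 8.02 to 25.7), the Polycomb group list (5.06 to 8.61) in each except with peaks strong in both replicates (4.45). Of the 16 motifs, 7 passed after stratification, the shuffled control CCGAT among them, and the Sp1/KLF site turned to 1.14. Replicates shared 36.7% of the strongest regions at 50 bp and 52.8% at 250 bp, as a wider reach must give more matches. For the other changes the cause was not tested. Of 709 values for single genes, lists, motifs, arms and location classes, 666 kept their side, 24 passed newly, 18 no longer passed and 1 turned, with turns counted only where a value passed the threshold. Read depth is unknown and its effect was not examined.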

Other observations

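Tests chosen only after the result was seen are those of ribosomal protein ranks, of windows along the arms, of candidates in and around ash1, of pooled housekeeping lists, and of the 7-mers.

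Ribosomal protein promoters stood higher in replicate 4 than in replicate 2. Among promoter peaks with a candidate in both replicates, 50 of 56 at ribosomal protein genes (89.3%) had the stronger rank in replicate 4, against 421 of 776 elsewhere (54.3%), an odds ratio of 7.01 (95% interval 2.96 to 20.3, p = 7.82e-08, two-sided Fisher exact test). RpL23A ranked 230 in replicate 2 and 15 in replicate 4, and RpL14 ranked 103 and 16. Mean GC content was 45.1% at the ribosomal protein peaks and 43.7% at the others. The 1567 strongest regions of replicate 4 were also richer in GC than those of replicate 2 (45.8% against 41.9%). Ranks were not compared at equal GC content, so a part of GC content in this shift was not tested.

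The bithorax complex held more peaks than each window of its length tested elsewhere. Of 13035 windows of 316 kb placed every 10 kb on the 5 long arms without overlapping it, none had 24 peaks, the median was 3 and the highest 21. None had its 363 candidates either, with 283 the highest. For the Antennapedia complex, 9.95% of 13020 windows had at least its 9 peaks.

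The strongest region, beside the 3' end of ash1, could have a technical origin, as the tagged line carries an altered ash1 gene. Extra copies of the whole gene, if missing from the control, would by themselves raise candidates inside ash1 to a similar rank. Free text in the labels speaks of an input control for flies with the tagged Ash1. Whether the control lacked such copies is therefore not settled. The strongest candidate inside ash1 ranked 6612 in the pooled list and 5575 in replicate 4, and replicate 2 had no candidate there. If an even rise would be ranked so high, this argues against such copies as the whole cause. Within 20 kb of the summit there were 20 other candidates in replicate 4 and 9 in replicate 2, at the 87.0 and 53.6 percentiles of 40 kb windows of 3L, which does not decide on a partial contribution of copies. That, copies of a shorter stretch, sequence of the tag and binding at the CG14100 promoter stay open, and no biological explanation was tested.

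Ribosomal protein promoters may be bound for a reason particular to them, as a hypothesis. Mitochondrial ribosomal protein, initiation factor and proteasome genes, pooled into 1 list, had an odds ratio of 1.19 (95% interval 0.632 to 2.12), below the interval of the ribosomal protein list, which argues against a property of housekeeping promoters in general. Peaks of close neighbours account for few cases, since 94.8% of the bound ribosomal protein genes (55 of 58) were the gene nearest to their peak. Compared within 5 classes of GC content, their promoter candidates still passed more often than others (Mantel-Haenszel odds ratio 13.9, 95% interval 9.09 to 21.3). Very high transcription, which can raise ChIP signal without binding, was not measured here and stays open.

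For the low overlap of the strongest regions of the replicates, none of 3 technical explanations was borne out as the chief source. A reach of 250 bp in place of 100 bp added 7.40 percentage points, too little for misplaced summits, and only 34.1% (replicate 2) and 40.4% (replicate 4) of the 856 unshared regions of each replicate had a match among the 4701 strongest of the other. Mean GC content differed over the whole lists, 41.9% and 45.8% in the 1567 strongest regions of replicates 2 and 4, and 44.1% and 47.7% in the others. Among the strongest, unshared regions stood further apart (40.4% and 47.3%) than these means, with shared ones at 43.6%. Shared regions are largely the same sequence in both replicates, so the difference must fall on the unshared ones. With equal numbers of regions taken from each of 5 GC classes in both replicates, 47.6% were shared (95% interval 45.1 to 50.1) in place of 45.4%. This argues against unequal numbers per GC class as the chief source. Mean GC content was then 43.3% and 44.0%, and ranks within a class were unchanged, so effects within classes were not tested. Such effects, and differences between libraries or embryo collections, stay open, as the labels give no library batch and no biological explanation was tested.

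Sequences of 7 bases found on chromosome 2 were tested on the other arms, under the hypothesis that peaks share sequence features beyond that chromosome. The 3 leading ones were GTAAATA, CTCTCTC and ACACTGA. All 3 were more frequent in the 976 peaks of the other arms than in other candidates there (Fisher exact tests), with odds ratios of 2.18 (95% interval 1.73 to 2.73, adjusted p = 4.39e-10), 2.36 (1.90 to 2.90, adjusted p = 2.89e-13) and 1.962 (1.44 to 2.62, adjusted p = 2.01e-05). The sequences had been seen in peaks of all arms before the split was made, so the test is not independent. It was also not stratified by promoter or GC content, in which peaks and other candidates differed. Whether the 7-mers differ apart from that was not tested. CTCTCTC is a GA repeat on the other strand, and which factors may bind the others was not tested.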
